A study of Mus musculus with 18 samples.

How the data were processed

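Copy number was measured in tail DNA of 9 mice on 18 Agilent 2-colour arrays, each against the same reference male. The mice were grouped from the labels as 1 sire, 1 dam and 7 progeny. Per the file headers, the scans were read with Feature Extraction 12.1.0.3, which gave background-subtracted, spatially detrended and linearly dye-normalised intensity values in each channel, and probe positions on mm9. The scanner files, per the file headers, also hold a log10 ratio of Cy5 over Cy3 made from these processed intensities, which was used only to check them. The authors' deposited value table holds a log2 ratio per spot. Set against the scanner values it was log2 of reference over mouse, with slopes of 0.946 to 1.00 in size and column medians from -0.003 to 0.018. A small further correction in it stays unknown.

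Ratios were computed from the processed intensities as log2 of mouse over reference, with the sign turned by the dyes in the labels. Control spots and outlier-flagged spots (121 to 1084 per array) were left out, spots of one probe were averaged, and each array was centred on its autosomal median. No spot was saturated. The 966371 spots gave 950749 probes, of which 36 lay on unplaced contigs. The 2 arrays of a mouse were averaged, and a dye effect equal on both arrays cancels in this mean. With the sign turned, the 2 arrays correlated negatively across autosomal probes in all 9 mice, from -0.36 in the sire to -0.02 in progeny 5. They thus did not reproduce each other probe by probe. Each chromosome was split by penalised least squares with a penalty factor of 2 times the log of the probe number times the variance. A segment was called with at least 3 probes, a mean of at least 0.3 in size and both arrays on the same side by at least 0.15. Calls of one sign that overlapped were merged into regions. A mouse was a carrier at 0.5 or more of the largest region mean among called mice. As a further comparison, chosen after the data were seen, the probe values of each mouse were shuffled 100 times within chromosomes, both arrays together, and called in the same way. This keeps each probe value and removes the order of probes. Each mouse and region was tested against 10000 random windows of as many probes in the same mouse, two-sided, with Benjamini-Hochberg adjustment over 1296 tests. Windows were not kept clear of called regions. The p describes a window within a mouse after the region was picked, so it does not account for the search. The strongest mouse had an adjusted p under 0.05 by this test at all 144 regions.

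Probes were tested with limma 3.58.1 in R 4.3.3, with 1 value per mouse. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0. The segmentation was tested on simulated data, with known shifts added to the half-sum of each mouse. Of 900 gains of 0.58 over 3 probes 61.3% were recovered, and over 10 probes 99.7%. For losses of -1.0 over 3 probes the share was 98.2%. In progeny 7, 5 of 100 gains over 3 probes and 97 of 100 over 10 probes were recovered. The half-sum has a larger neighbour spread than the dye-swap mean in each mouse, so these shares may differ there. The limma step recovered 100% of 200 probes shifted by -0.3 in the family test and 1.5% in progeny against parents, on 50000 simulated probes. The simulated mice had independent noise. The real mice are related, share 1 reference and correlated at up to 0.53 across probes, so these shares may not carry over.

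The 10 regions with the largest called means were described in full by a rule set before the data were examined. Regions of 10 or more probes, and losses carried by the dam and not the sire, were added after their values were seen. Alternatives changed the thresholds, the penalty, the background correction, the centring, the dim-probe filter, the dye orientation, the carrier level and the mice included. The files hold median and not mean signals per channel, so normexp with an offset of 50 ran on median signals. Gene names could not be assigned, because the positions are on mm9 and the reference table used here is on another assembly. The 9 gene lists and the named genes were therefore not computed. The later high-density arrays and copy number assays that the design mentions were not analysed here.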

Results

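Genomic DNA from the tails of 9 C57BL/6 mice of one family was compared with DNA of 1 reference male of the same colony on 2-colour oligonucleotide arrays, which read the ratio of DNA amount at each probe (array comparative genomic hybridisation). The family had 1 sire, 1 dam and 7 progeny. The study searched for copy number changes in offspring of males kept under gamma rays at 0.05 mGy per day for 400 days. The series title describes an irradiated male at this dose, whereas the design text calls the sire of this family non-irradiated in one place, so the exposure of the sire is left open here. No unirradiated family was analysed here, and no comparison below bears on radiation. Each mouse was hybridised on 2 arrays with the dyes swapped, giving 18 arrays, and the pair counted as 1 replicate. The arrays carried 950622 autosomal probes at a median spacing of 2053 bp, 68 probes on X and 23 on Y. The median background-subtracted Cy3 signal per array ranged from 46.0 to 231.7, and both arrays of progeny 7 were the dimmest. The spread between neighbouring probes in the dye-swap mean ranged from 0.09 in the sire to 0.19 in progeny 7 on the log2 scale. The number of arrays limits the precision, and each SE below is over probes within a mouse. Such an SE covers the spread between probes, and leaves out error common to a whole array and the error of the shared reference.

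Ratios are log2 of mouse over reference, opposite in sign to the submitters' value table. X probes had a median of 0.95 in the dam and -0.01 in the sire. Progeny 1 and 2 had X medians of -0.01 and -0.02, and progeny 3 to 7 had 0.96, 0.98, 0.98, 0.95 and 0.92. Y probes had a median of -2.34 in the dam and -0.02 in the sire. In progeny 1 to 7 the Y medians were -0.02, 0.01, -2.94, -2.61, -2.85, -2.13 and -1.94. Progeny 1 and 2 thus had the X and Y ratios of the sire, a male, and progeny 3 to 7 those of the dam, a female. Over the 19 autosomes the 171 medians per mouse and chromosome lay between -0.01 and 0.01, against 0.58 for a whole-chromosome gain of 1 copy. None of the 19 chromosomes had a progeny standing apart from the other 6 by Dixon's ratio.

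2 regions on chromosome 14 had less DNA in all 9 mice than in the reference male. The first ran from 53387255 to 53994906 (mm9, 69 probes), with a mean of -0.52 ± 0.02 (SD, n = 9 mice) and values from -0.55 in progeny 3 to -0.50 in progeny 6. Inside it, the probes from 53714075 to 53759064 formed a separate lower segment in the dam and progeny 1, 2, 3, 4 and 6, at -1.05 to -0.91. These probes were also low in the sire, progeny 5 and progeny 7, with single probes from -1.108 to -0.635, inside longer segments. The region mean thus covers more than 1 level. The second ran from 54073238 to 54386805 (39 probes), with a mean of -0.37 ± 0.07 (SD, n = 9 mice) and values from -0.45 in progeny 2 to -0.27 in progeny 7. In each of the 9 mice the adjusted p by the random-window test was 0.0012 at the first region and 0.00167 at the second. The smallest unadjusted p that this random-window test can give is 0.0001. This count addressed differences that belong to the reference animal. Under 8 alternatives only 1 region was carried by all 9 mice. In 6 of them both regions were joined into a single one carried by all 9 mice, and in 2, normexp background correction and the stricter carrier level, progeny 5 and 7 missed the carrier level in the second region.

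**Figure D1:**
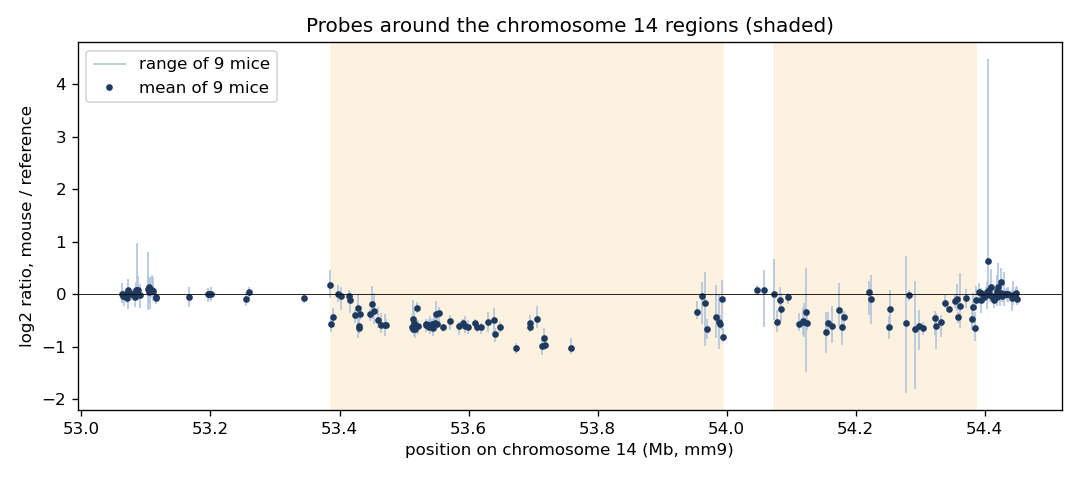
Log2 ratio of mouse over reference (vertical axis) against position on chromosome 14 in Mb, mm9 (horizontal axis); points are means of 9 mice, vertical lines the range of the 9 mice, and shading the 2 regions carried by all 9 mice. Many probes in the first region lie near its mean of -0.52, some near its start lie near 0, and those from 53714075 to 53759064 lie lower. Most flanking probes lie near 0.

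Probe by probe, 636 of 948192 autosomal probes differed from the reference over the 9 mice (limma, Benjamini-Hochberg adjusted p of 0.05), 450 higher and 186 lower in the family. Of the 186 lower probes, 78 lay inside the chromosome 14 regions, with a median of -0.58. With normexp background correction 591 were higher and 504 lower, and with loess 54 were higher and 114 lower. With scan day as a random block 157 probes passed, 69 higher and 88 lower. Leaving out 1 progeny gave 267, 128, 135, 113, 153, 162 and 282 probes for progeny 1 to 7, and more were lower than higher without progeny 2, 3, 4, 5 or 6 (83, 84, 81, 92 and 91 lower). Higher probes kept the majority without progeny 1 (163 higher, 104 lower) and without progeny 7 (165 and 117). The progeny alone gave 5759, 5214 higher and 545 lower, and probes well above background gave 1310 higher and 400 lower. The test leaves out the spread of the reference, which is 1 animal, and treats the 9 related mice as independent.

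At 36 of the 144 regions, 34 gains and 2 losses, the dam and progeny 3 to 7 all lay beyond the sire, progeny 1 and progeny 2. The X and Y probes showed the same split, with higher X and lower Y ratios in the dam and progeny 3 to 7. Among the progeny the split also follows scan day, with progeny 1 and 2 on day 2 and progeny 3 to 7 on days 3 to 5. The sire and the dam were both scanned on day 1 and lay on opposite sides. The 3 regions with the widest gap between the nearest mice of both sides, 0.17 or more, are described here. At the other 33 the gap was 0.003 to 0.14. On chromosome 3, from 25417435 to 25432738 (3 probes), the dam had -1.77 ± 0.24 (SE) and progeny 3 to 7 had -1.70, -1.71, -1.67, -1.56 and -1.41, whereas the sire, progeny 1 and progeny 2 had 0.09, 0.05 and 0.09. On chromosome 8, from 102132083 to 102242602 (38 probes), the dam had 0.28 ± 0.03 (SE) and progeny 3 to 7 had 0.23, 0.29, 0.27, 0.23 and 0.35. The sire, progeny 1 and progeny 2 had -0.02, 0.04 and 0.02 there. On chromosome 14, from 61798066 to 61804726 (5 probes), the dam had -0.38 ± 0.11 (SE) and progeny 3 to 7 had -0.37, -0.44, -0.27, -0.37 and -0.20. The value of progeny 7 there missed the level set for a carrier. With normexp background correction none of the 3 was called in the mouse with its strongest value. The values were -2.01 in the dam on chromosome 3, 0.19 in progeny 7 on chromosome 8 and -0.41 in progeny 4 on chromosome 14. On chromosome 3 the dam was thus lower than the -1.77 of the main setting, so the missing call there was not a weaker ratio. In the main setting progeny 3, 4 and 6 were not called there either. The chromosome 8 region, and that on chromosome 14, were chosen after their values were seen, and that on chromosome 3 was the region with the largest called mean.

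**Figure D2:**
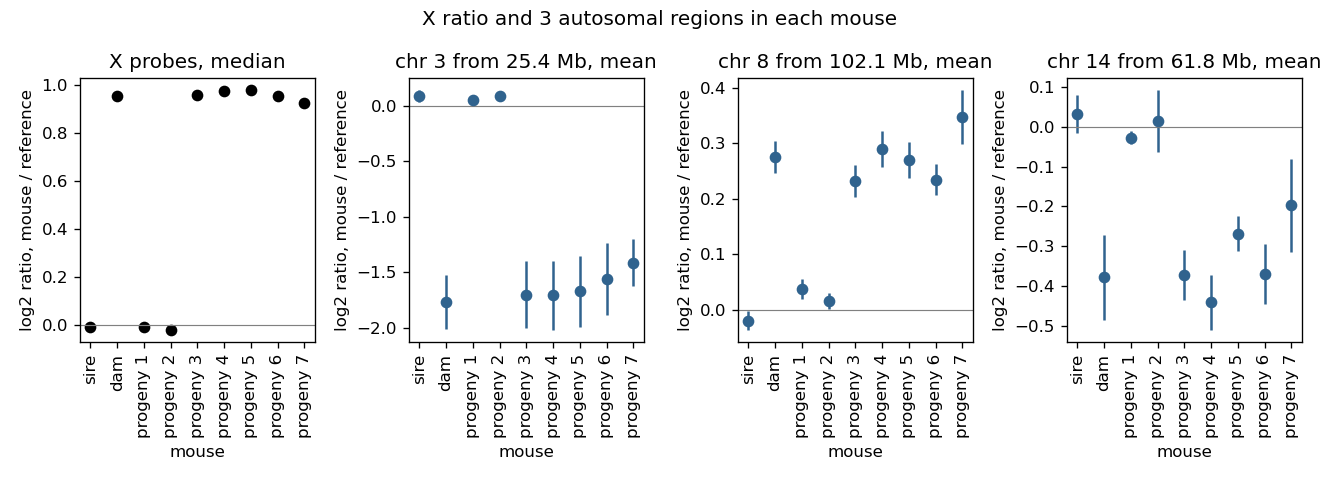
Median log2 ratio of the X probes (left) and mean log2 ratio of mouse over reference in 3 autosomal regions, 1 point per mouse; bars are SE over probes. The dam and progeny 3 to 7 lie apart from the sire, progeny 1 and progeny 2 in each panel, least clearly for progeny 7 on chromosome 14 at -0.20.

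Transmission was examined at 33 regions carried by exactly 1 parent, 29 by the dam and 4 by the sire. Most of them were called only in progeny, with the parent reaching the carrier level. Those had at least 1 carrier progeny by the way they were picked, so an even chance is not a fair expectation for them. No region passed the exact two-sided binomial test of carriers among the 7 progeny against an even chance (lowest adjusted p = 0.103). The smallest unadjusted p that 7 progeny allow in this binomial test, 0.0156, was reached at 5 regions. Each was called in the parent alone and had no carrier among the progeny. At least 11 regions at that p would have been needed for any to pass after adjustment, so the test could hardly have found a departure and does not speak for an even chance.

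The search for changes in progeny that neither parent carries gave 109 regions, 107 gains and 2 losses. Of these 109, 88 spanned 3 or 4 probes. While 106 were called in 1 progeny, only 40 were carried by 1 progeny alone. At some the dam fell just short of the carrier level, as on chromosome 6 from 36858055, with 0.323 against 0.65 in progeny 5. The number of gains called over all 9 mice, 140, lay within the 98 to 162 called when the probe values of each mouse were shuffled within chromosomes (100 shuffles). The longest gain called in progeny 4 alone lay on chromosome 9 from 91822039 to 91847301 (25263 bp), with a mean of 0.41 ± 0.03 (SE) over 12 probes, all 12 above 0. Its arrays gave 0.37 with the mouse in Cy5 and 0.45 with the mouse in Cy3, and the other 8 mice lay between -0.05 and 0.10. The random-window test gave an adjusted p of 0.00167. The region was picked for its high mean in this mouse, so that p lends it no support. The other gains of 10 or more probes were on chromosome 9 from 80424970 to 80452809 (13 probes, 0.35 in progeny 5), on chromosome 2 from 110066997 to 110101804 (11 probes, 0.31 in progeny 7) and on chromosome 2 from 18634136 to 18649911 (10 probes, 0.35 in progeny 5, with 0.29 in progeny 7 and 0.23 in progeny 4). These 4 were chosen after their values were seen. A gain of 10 or more probes was called in 0 of 100 shuffles of progeny 4, 40 of progeny 5 and 45 of progeny 7. With normexp background correction the chromosome 9 gain of progeny 4 was 0.46, and the other 3 were no longer called, at 0.14, 0.06 and 0.11. Median signals averaged 219.5 in progeny 4, 107.4 in progeny 5 and 60.8 in progeny 7, and the normexp offset shrinks ratios more where signals are dim. The drop under normexp thus does not by itself set the other 3 apart from the gain of progeny 4. After regression on the other 8 mice the gain of progeny 4 was 0.40, and the others were 0.18, 0.27 and 0.16. Without progeny 5 the count was 56, with normexp background correction 30, with a minimum of 5 probes 20, and after regression of each mouse on the other 8 it was 38.

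**Figure D3:**
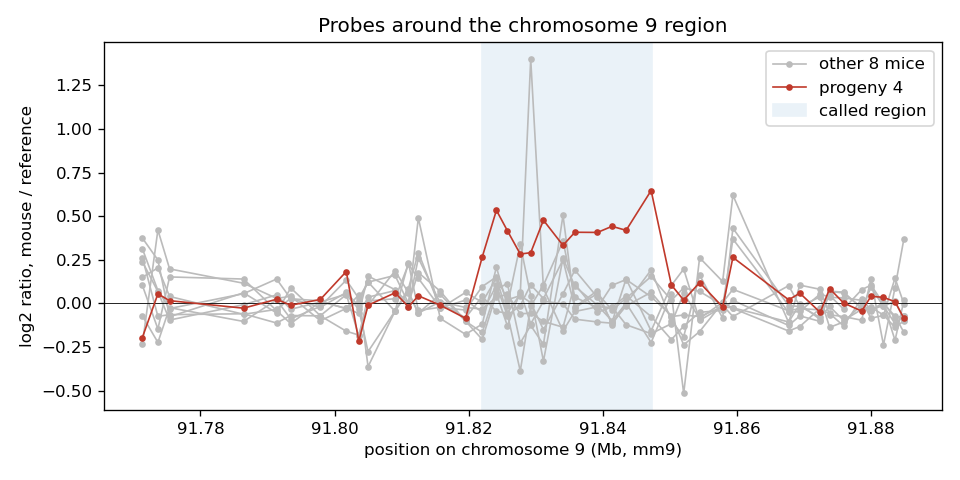
Log2 ratio of mouse over reference (vertical axis) for each probe against position on chromosome 9 in Mb, mm9 (horizontal axis), in progeny 4 (red) and the other 8 mice (grey); shading marks the called region. All 12 probes of progeny 4 inside it lie above 0, with a mean of 0.41.

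The remaining 8 of the 10 regions with the largest called means were gains led by progeny 7, the mouse with the dimmest arrays. In progeny 7 the means were 0.83 on chromosome 1 from 94672378 to 94679803 (5 probes), 0.91 on chromosome 13 from 94439270 to 94443332, 0.90 on chromosome 8 from 99723943 to 99726901 and 0.81 on chromosome 2 from 76728907 to 76732544. Further means of progeny 7 were 0.81 on chromosome 10 from 90643581 to 90647036, 0.78 on chromosome 12 from 41482373 to 41485964, 0.77 on chromosome 3 from 16870548 to 16874722 and 0.76 on chromosome 5 from 10462820 to 10472863. Each but the first held 3 probes, and each had an adjusted p of 0.0012 in progeny 7 by the random-window test. That test does not account for the picking of these regions by their high means. The SE over probes reached 0.50 for chromosome 13, where 2 of 3 probes were above 0, and with well above background probes this region turned to -0.091. With normexp background correction none of the 8 was called, and the means fell to 0.14, 0.03, 0.07, 0.09, 0.08, 0.11, 0.10 and 0.05 in the order given.

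Over all 9 mice 195 segments were called, 140 gains and 55 losses, and merged into 144 regions. By mouse the counts were 9 in the sire, 13 in the dam and 10, 17, 20, 37, 63, 5 and 21 in progeny 1 to 7. In the half-sum of the swapped arrays, in which copy number cancels, 22 segments were called, 4 gains and 18 losses. Its count was 2 with normexp background correction, 6 with the submitters' value table, 10 with well above background probes, 15 with loess and 11 with wave correction. The half-sum had a larger neighbour spread than the contrast in each mouse (0.14 against 0.09 in the sire), and so a higher penalty, which lowers its count. The shuffled probe values, called with the spread of the real order, gave a median of 128.5 gains and 7 losses, with 1 to 13 losses against the 55 called. Of those 55 losses, 44 lay in the 2 chromosome 14 regions shared by all 9 mice. The number of losses elsewhere lay within the 1 to 13 of the shuffles. This compares counts only, and not position or size. The chromosome 3 loss from 25417435 was called in the dam, progeny 5 and progeny 7 (-1.77, -1.67 and -1.41). The chromosome 14 loss from 61798066 was called in progeny 3 and 4. Called with their own spread, the shuffled values gave 95 to 156 gains and 1 to 12 losses. Of segments with 10 or more probes, 29 were called in the contrast and 0 in the half-sums. Of these 29, 24 lay in the 2 chromosome 14 regions shared by all 9 mice, and 5 lay elsewhere, 1 in progeny 4, 2 in progeny 5 and 2 in progeny 7. Gains made up 71.8% of calls in the main setting, 41.3% with normexp background correction and 60.9% with loess. Without progeny 5 there were 89 regions.

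**Figure D4:**
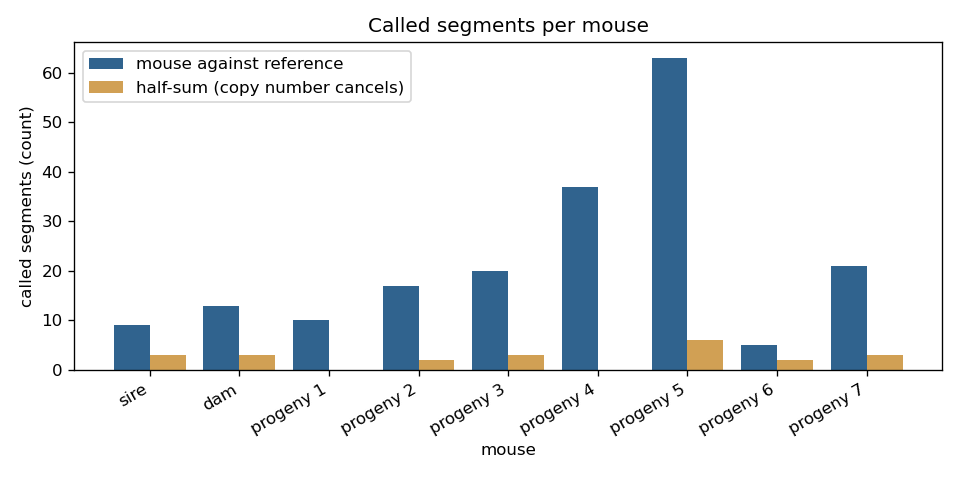
Number of called segments (vertical axis) in each mouse against the reference (blue) and in the half-sum of its 2 arrays (orange). Progeny 5 has 63 and progeny 4 has 37 segments, against 6 and 0 in their half-sums.

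No probe passed the test for a difference between the 7 progeny and the 2 parents (limma, 0 at an adjusted p of 0.05, 29510 at an unadjusted p under 0.05). In simulated data this comparison recovered 1.5% of probes shifted by -0.3 in all progeny, so the 0 does not show that such differences are absent. Without the sire 3 probes passed, and without the dam 615. Both parents were scanned on day 1 and the progeny on days 2 to 5, so scan day cannot be separated from this comparison. A random block for scan day also gave 0, which cannot check for an effect of the day.

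Single probes were tallied because the study picked probes aberrant in both dye orientations. Over the 9 mice 21380 probe readings passed 0.5 on both arrays in the direction of a copy number difference, 18784 gains and 2596 losses. In the direction of a dye effect 17615 passed. Progeny 7 gave 9498 and 10217, and progeny 5 gave 6623 and 2028. With normexp background correction 4725 passed in the copy number direction and 7110 in the dye direction.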

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

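The tests of explanations in this part were chosen after the results were seen, whereas the normexp and well above background settings were planned. For the shuffles, what would count was set before they were run. Among the 7 progeny 41 series of values were searched for a single progeny far from the other 6, and 9 stood apart. Chance gives about 1 in 20, and the region series are not a fair draw, since regions were called for a high value in 1 mouse. Progeny 7 stood apart with 0.81 on chromosome 2 from 76728907, 0.31 on chromosome 2 from 110066997, 0.77 on chromosome 3 from 16870548 and 0.76 on chromosome 5 from 10462820. It also stood apart with 0.90 on chromosome 8 from 99723943, 0.78 on chromosome 12 from 41482373 and 0.91 on chromosome 13 from 94439270. With normexp background correction these 7 values were 0.09, 0.06, 0.10, 0.05, 0.07, 0.11 and 0.03, and none was called, and chromosome 13 was at -0.091 with well above background probes. Progeny 5 stood apart with 0.35 on chromosome 9 from 80424970, where the other progeny lay between 0.06 and 0.17, and with normexp it had 0.14. Progeny 5 and 7 had the dimmest arrays, where the normexp offset shrinks ratios most, so these drops do not decide.

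Progeny 4 stood apart on chromosome 9 from 91822039, with 0.41 against -0.05 to 0.10 in the other progeny. Random noise of single probes is argued against by a called gain of 10 or more probes in 0 of 100 shuffles of the probe values of progeny 4. Noise shared by neighbouring probes was not tested in this way. A probe bias shared between DNA extracts stays open. The mean was 0.40 ± 0.03 (SE) after regression on the other 8 mice, but the region was picked as carried by progeny 4 alone, so the other mice are low there by that choice and the regression decides nothing. The same holds for progeny 5, with 0.006 ± 0.06 (SE) here and 0.14 to 0.56 at the 27 other gains called in progeny 4 alone. One extra copy in every cell would give 0.57 from the X ratio of this mouse, above the mean and above both arrays, if the probes here respond as the X probes do. An extra copy in part of the cells, or a weaker probe response, stays open and was not tested. Whether irradiation of the sire plays a part was not tested, since no unirradiated family was analysed here.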

How the results depend on the processing

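The regression on the other 8 mice and the settings without a progeny were chosen after seeing the data; the others were planned. The cause was not tested where a count moved, except that fewer probes, mice or arrays enter by construction. Called segments (195), regions (144) and regions in progeny and neither parent (109) became 59, 24 and 20 with at least 5 probes, 76, 38 and 28 with penalty 3, 75, 43 and 30 with normexp, 72, 41 and 24 with the mouse in Cy5 only, 95, 69 and 46 in Cy3 only, and 62, 51 and 38 after the regression. A size threshold of 0.4 gave 129 segments and 92 regions. Without each progeny in turn, segments ranged from 132 to 190, regions from 89 to 143 and regions in neither parent from 56 to 108, lowest without progeny 5. Regions carried by all 9 mice fell from 2 to 1 with a size threshold of 0.2, penalty 3, normexp, well above background probes, loess, either dye orientation alone and the stricter carrier level; with normexp and the stricter level progeny 5 and 7 missed the carrier level in the second region, and with the other 6 both regions were joined. Probes differing from the reference (636) numbered 157 with scan day as a random block, 5759 in the progeny only, 1095 with normexp, 168 with loess, 1710 with well above background probes and 113 to 282 without each progeny. Progeny against parents (0) gave 3 without the sire and 615 without the dam, where the lone parent is assumed to vary like the progeny, and 0 without each progeny. Single probes in the copy number direction (21380, against 17615 in the dye direction) numbered 102549 at 0.3 (187190), 3001 at 0.8 (1258) and 4725 with normexp (7110), so the dye direction led at 0.3 and with normexp. Of 203 values of named regions under alternatives, 125 were still called, 77 kept their sign without a call, and 1 turned: chromosome 13 from 94439270 in progeny 7, at -0.091 with well above background probes. The chromosome 9 gain of progeny 4 from 91822039 and the first chromosome 14 region were called under all 12 alternatives. For chromosome 8 from 99723943 no probe was well above background on every array, so that setting gave no value. Dim arrays limit progeny 7 most, with 20025 and 7697 spots not well above background. No paired analysis was possible because the groups share only replicate number 1. The gene list result and named genes were not run.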

Other observations

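All tests in this part were chosen after the results were seen, and for the shuffles what would count was set before they were run. At the 3 regions whose ratios separate the mice as the X ratio does, a candidate explanation is sequence shared with a sex chromosome. The Y ratio separates the mice in the same way. On chromosomes 3 and 14 the dam and progeny 3 to 7 were low, the direction of the Y ratio. On chromosome 8 they were high, the direction of the X ratio. Sharing with X was not told apart from sharing with Y by a test. The prediction was that carrier status and a raised X ratio would go together in 7 of 7 progeny at all 3 regions. This held on chromosomes 3 and 8, and in 6 of 7 on chromosome 14, where progeny 7 had -0.20 ± 0.12 (SE), so the prediction as written was not met. The match also defines the pattern and tests nothing by itself, so sequence shared with a sex chromosome stays open, with no mm9 sequence used here to search. The 33 other regions that separated the mice in this way were all gains, so for the chromosome 8 gain the split alone does not set sharing with a sex chromosome apart from what acts at those gains. For chromosome 3, both copies lost in the dam and both present in the sire and reference would leave 1 copy in every progeny, and 2 of 7 progeny lay near 0. A sire and a reference that both carry the sequence on 1 chromosome only, with none in the dam, were not tested and could give the same values. For chromosome 14, a loss of one copy transmitted by the dam is argued against by 5 of 5 carriers falling more than 2 SE short of its level. For chromosome 8, a gain of one copy transmitted by the dam is argued against by 6 of 6 carriers falling more than 2 SE short over the whole region. Over the 5 probes called in progeny 3 for their high mean 1 of 6 did, and over the other probes 6 of 6. Both rest on an SE over probes and on these probes responding as the X probes do, and other copy numbers stay open.

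Small gains were called most often in progeny 4 (30) and progeny 5 (58), 88 in both together. Random noise of single probes stays open, since 61 to 111 gains (median 83.0) were called in these mice in 100 shuffles of their probe values. Chance placement of deviating probes thus gave about as many gains. The 1 gain in their half-sums does not decide, because the half-sum carries a higher penalty. Copy number gains private to progeny 5 would leave progeny 4 above 0 in about 0.5 of the regions called gained in progeny 5 alone. Progeny 4 was above 0 in 55 of 55. The 0.5 assumes that both mice vary independently, but they correlated at 0.45 across probes and share the reference. Regions picked for a high progeny 5 thus lean above 0 in progeny 4, and the count does not decide. After each mouse was regressed on the other 8, 4 of the 88 gains were still called. A probe bias shared between DNA extracts may therefore account for the raised probe values, with chance placement bringing them together, and a shared origin other than the extracts was not tested. At those 55 regions the median was 0.54 in progeny 5, 0.27 in progeny 7, 0.23 in progeny 4, 0.16 in progeny 3, 0.12 in the dam and -0.04 in the sire.

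Across probes, which are not independent replicates, the dam and progeny 2 correlated at 0.53 and progeny 4 and 5 at 0.45, the 2 highest of the pairs of mice. The 36 probes on unplaced contigs had medians from -0.01 in progeny 3 to 0.12 in progeny 7.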
